A study of Oncorhynchus mykiss with 28 samples.

How the data were processed

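RNA of rainbow trout (Oncorhynchus mykiss) from liver, kidney and gills was measured on 28 Agilent arrays with 1 colour (Cy3), 1 array per sample. The labels place each array in 1 of 14 groups of 2 by tissue, stocking density and strain. The densities were moderate (MD, 10 kg of fish per cubic metre), elevated (ED, 18) and high (HD, 35), and the strains were Born and Troutlodge. ED was measured in liver only, so liver had 12 arrays and kidney and gills had 8 each. RNA of 5 fish was pooled for each array, and fish were sampled on day 8, per the labels. The experiment was run once per strain, so strain cannot be separated from the run, the age and the sex of the fish. Nothing in the labels says that the pools of a group came from separate tanks, so p-values measure only the spread between these pools, which may be technical, and tank and density go together.

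The deposited scanner files hold the intensity of each spot on a linear scale, made with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. Per the file headers, the processed intensity had its background subtracted by spatial detrending, was detrended multiplicatively within the array, and had small values set to a surrogate, with no normalization between arrays. The deposited value table held an intensity that was equal, spot by spot, to the background-subtracted signal of the scanner files. It was therefore linear, neither centred nor normalized between arrays, and no scale, centring or direction stayed unknown; the medians of its columns ran from 5.9 to 28.9. The mean and local background intensities of the deposited files, which are not background-subtracted per the file headers, were used only for an alternative background correction. The scanner's marks for spots above background, saturated spots and outlier spots were used as given.

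Each array had 62976 spots, of which 1319 control spots were left out, and 49255 distinct probes. The files give exactly 1 gene symbol for 4743 probes (9.6%), several for 0 probes, and a protein name in the description of 20156 probes. Neither was given for 28987 probes. The descriptions of 28275 probes name Atlantic salmon (Salmo salar), so many probes were designed on sequences of that species and their gene names are those of the array's design, which can be old. Of the probes' accessions, 0 were found among the 72772 entries of the rainbow trout RefSeq gene table (assembly USDA_OmykA_1.1), so names were kept as the files give them. No genome was used here.

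Between 38.3% and 40.9% of probes lay well above background on the liver arrays, 49.2% to 60.9% on the kidney arrays and 48.2% to 53.6% on the gill arrays. No spot was saturated, and 23 to 69 outlier spots per array were left out. The pools of a group correlated across probes with r between 0.985 and 0.991, and no pair of arrays held identical values. The number of arrays limits the precision.

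The log2 of the processed signal had each array's 75th percentile subtracted. Because under 50% of the liver probes were detected, that percentile was taken over the probes well above background on all arrays of the tissue (15650 in liver, 21718 in kidney, 21754 in gills). Replicate spots of a probe were averaged. A probe was kept where it lay above background on every array of at least 1 group of strain and density, which left 20718 probes in liver, 25547 in kidney and 25357 in gills. Each tissue was fitted with lmFit and eBayes (with a trend on mean signal) of limma 3.58.1 in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Density and strain comparisons used an additive model of strain and density. Comparisons within a strain used group means, as did the difference between strains in their density effect, called the difference between strains for short. The difference in the density effect between tissues was fitted over all 28 arrays. All these tests were two-sided.

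A total of 37 lists of genes (pathways, complexes and cell type markers) was fixed before the data were examined, as were the tests, the other settings to try and the rule for naming genes. A list's members were found by gene symbol. Because so few probes carry a symbol, members were also found by protein name. The name patterns were written after the annotation had been seen and before groups were compared, and the choice to report lists found this way was made after results had been seen. Lists with at least 5 measured members were tested with camera of limma at a preset correlation of 0.01 between genes, with 1 probe per gene (the brightest in the tissue). Camera with an estimated correlation was run beside it, as was fry, which tests a list against no change and not against other genes. A list's shift is its members' median log2 change minus the median over all genes.

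The named genes were chosen by a fixed rule. For each density comparison these were the 10 largest rises and the 10 largest falls among probes with exactly 1 symbol, past the threshold and with the same sign in both strains, 1 probe per gene. Where fewer than 5 passed in a direction, the 5 with the smallest p are given as not passing. For each list described, 2 to 4 members with the smallest p were taken, and for strain differences the 5 largest in each direction. The genes with the highest signal of the hepatocyte, kidney tubule and gill epithelium lists checked the labels of the tissues. Where all pools of a group lay below background, a fold is given as "at least", from the bright group's mean against, in each dim pool, the higher of the probe's own signal and the lowest signal among probes well above background on that array. Where 2 probes of a gene differed, the brighter was used for lists.

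The files give 6 slides, numbered 1 to 6, and the arrays of slide 6 were scanned on a later day. Slide was fitted as a block, and contrasts within a slide were computed where a slide held both groups. The settings chosen beforehand were normexp background correction with an offset of 50 and quantile normalization, quantile normalization of the processed signal, the deposited value table, no filter or a stricter filter on dim probes, a replicate block, group means, no trend, all 28 arrays in a joint fit, 1 replicate number at a time, the mean of all probes of a gene, and leaving out each array in turn. A further 5 alternatives were chosen after seeing the data: the percentile over all probes, list members by protein name, the kidney comparison without the array with the highest share of detected probes, the liver comparison without arrays rich in pancreas transcripts, and the difference between tissues in a joint fit.

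The fits were tested on simulated data with known changes of 1.5-fold in 67 probes, 2-fold in 67 and 4-fold in 66. In the simulation of liver HD against MD, 29.9% of probes changed 1.5-fold, 52.2% of those changed 2-fold and 87.9% of those changed 4-fold were called, with 0 in the wrong direction. The corresponding shares were 28.4%, 67.2% and 87.9% for kidney and 31.3%, 59.7% and 81.8% for gills. For the difference between strains in their density effect in liver, 0%, 9.0% and 40.9% were called. For the comparison of the strains themselves in liver, the shares were 38.8%, 68.7% and 100%. With the cholesterol synthesis list lowered by 0.5 on the log2 scale among 17732 simulated liver genes, it was called in 20 of 20 simulations, and 4 of 600 tests of other lists were called. The simulated genes varied independently of each other. These shares therefore do not tell how often lists are called falsely where genes vary together. Tables were handled with jsonlite 2.0.0, the R package data.table in version 1.17.8, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, random blocks used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9.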

Results

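Transcript levels were compared between rainbow trout kept at different stocking densities, in liver, kidney and gills of a pair of strains, Born and Troutlodge. The question was which genes respond to crowding for 8 days at an elevated (ED) or high density (HD) against an uncrowded moderate density (MD). Each of the 28 arrays measured the pooled RNA of 5 fish. There were 2 pools for each strain and density, so a density comparison over both strains in a tissue set 4 pools against 4. Values are log2 signals relative to the 75th percentile of the array, and errors of log2 changes are standard errors of limma's fit.

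Genes known from each organ, with an exception among the keratins, marked the tissues as labelled. Serum albumin 2, the main plasma protein made by the liver, had a mean of 9.99 ± 0.20 (SD, n = 12 pools) in liver, -0.39 ± 2.50 (n = 8) in kidney and -2.66 ± 1.89 (n = 8) in gills. The sodium-phosphate cotransporter npt2a, which takes up phosphate in the kidney tubule, stood at 4.24 ± 0.20 in kidney and was above background in 1 of 12 liver pools and 0 of 8 gill pools. Keratin 13, a filament protein of surface epithelia, reached 6.39 ± 0.12 in gills against -3.87 ± 1.08 in liver and -1.93 ± 1.01 in kidney. The albumin level of kidney varied widely between pools, from 3.70 and 2.41 in the Troutlodge MD pools to -3.16 and -2.79 in the Born HD pools. Within a tissue, the first principal component carried 40.4% of the variance in liver, 43.5% in kidney and 42.7% in gills.

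**Figure D1:**
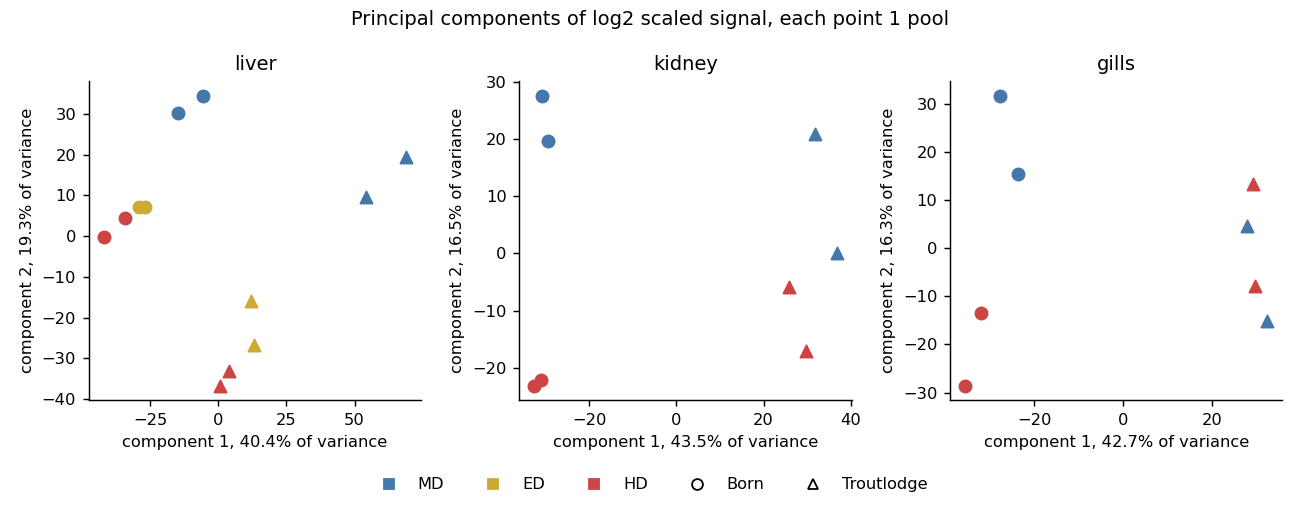
Each point is a pool of 5 fish on the first 2 principal components of liver, kidney and gills, from the probes above background on all arrays of the tissue. Scores have no unit, the share of variance is in percent on the axes, and points are coloured by density and shaped by strain. The first component separates the strains in each tissue, and in liver the MD pools also stand apart from the ED and HD pools of the same strain.

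In liver, genes of lipid synthesis fell at high density. Farnesyl pyrophosphate synthase (fpps), which makes the precursor of squalene, was 8.38-fold lower in HD than in MD, with means of 1.80 ± 0.49 and 4.87 ± 0.92 (SD, n = 4 pools each; log2 change -3.07 ± 0.43, adjusted p = 0.0011). Diphosphomevalonate decarboxylase (erg19), a step of the same pathway, was 7.34-fold lower (adjusted p = 7e-04). ELOVL6, which lengthens saturated fatty acids, was 8.87-fold lower (-3.15 ± 0.34, adjusted p = 0.00037) and acyl-CoA desaturase (SCD), which makes monounsaturated fatty acids, 3.88-fold lower (-1.96 ± 0.24, adjusted p = 0.00059). The rate-limiting enzyme of cholesterol synthesis, HMG-CoA reductase (hmdh), fell by 0.66 ± 0.11 on the log2 scale (adjusted p = 0.0025).

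Of 12 measured genes of cholesterol synthesis, 8 fell, 0 rose and 4 did not pass the test, and 9 fell when adjusted over the list alone. Their median lay at -1.31 relative to all genes (camera, adjusted p = 1e-06). That call was lost (adjusted p = 0.28 with an estimated correlation), and with normexp and quantile normalization the shift was -0.64. Cytosolic acetyl-CoA acetyltransferase (thic) changed by -1.03 ± 0.13 (adjusted p = 0.00062), and the sterol dehydrogenase NSDHL was at least 2.31-fold lower, above background in 4 of 4 MD pools and 0 of 4 HD pools (adjusted p = 0.0019). Among 10 measured genes of fatty acid synthesis, 7 fell and 3 did not pass, with 8 falling when adjusted over the list alone, and the list shifted by -1.31 (adjusted p = 1e-06; adjusted p = 0.06 with an estimated correlation). The fatty acid desaturase fadsd5 was 1.99-fold lower (adjusted p = 0.0011). A probe with the symbol lipe was 7.10-fold lower (-2.83 ± 0.48, adjusted p = 0.0027). Many symbols of this array, such as hs90a for HSP90AA1, are not human gene symbols, so which lipase lipe stands for is not settled here. Fatty acid oxidation and ketogenesis, with 15 measured members, shifted by -0.17 (adjusted p = 0.66), and 1 member rose and 1 fell. Adipocyte markers, 6 measured with lipe counted among them by its symbol, shifted by -0.56 without passing (adjusted p = 0.075), 2 of them lower, with -0.42 and -0.65 within slides 1 and 3. Their score was 0.20 to 0.85 in the MD pools and -0.46 to 0.02 in the HD pools.

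Chaperones of the cytosol and of the endoplasmic reticulum were also lower in HD livers. Heat shock protein 90 alpha (hs90a) was 6.57-fold lower (-2.72 ± 0.38, adjusted p = 0.0011), its activator AHSA1 2.90-fold lower (adjusted p = 0.00033), the collagen chaperone serph 2.40-fold lower (adjusted p = 0.0016), and the mitochondrial chaperonin hsp60 2.39-fold lower (adjusted p = 0.0028). Heat shock 70 kDa protein 4 (hsp74) changed by -2.49 ± 0.46 (adjusted p = 0.0043) and was above background in 2 of 4 HD pools and 4 of 4 MD pools. With normexp and quantile normalization, which shrinks changes of dim probes, hs90a stood at -1.70 and hsp74 at -1 on the log2 scale. Of 16 heat shock proteins and chaperones, 6 fell, 0 rose and 10 did not pass, and the same number fell when adjusted over the list alone. The list's shift was -0.46 (adjusted p = 0.0022; adjusted p = 0.32 with an estimated correlation). In the list of endoplasmic reticulum stress genes, 5 of 12 fell, 0 rose and 7 did not pass (7 fell when adjusted over the list alone). They included grp78, the main chaperone of that compartment (-1.76 ± 0.29, adjusted p = 0.0024), its partner dnjc3 (-1.76 ± 0.32, adjusted p = 0.0042), the secreted factor ARMET, also called MANF (-1.67 ± 0.35, adjusted p = 0.008), and asparagine synthetase (-1.36 ± 0.21, adjusted p = 0.0019). This list shifted by -0.99 (adjusted p = 3.9e-05; adjusted p = 0.31 with an estimated correlation), and by -0.53 with normexp, -0.54 with the value table and -0.44 with the mean of all probes of a gene.

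Subunits of the proteasome, the complex that degrades ubiquitin-tagged proteins, fell in the same livers. Of 24 measured genes, 8 fell, 0 rose and 16 did not pass, and 12 fell when adjusted over the list alone, among them PSMD7 (-0.95 ± 0.10, adjusted p = 3e-04), PSMA1 (-1.03 ± 0.17, adjusted p = 0.0026) and psd11 (-1.29 ± 0.23, adjusted p = 0.004). The list shifted by -0.50 (adjusted p = 3.8e-07; adjusted p = 0.32 with an estimated correlation). Among 27 genes of antioxidant defence and metal binding, 7 fell and 2 rose (7 and 3 when adjusted over the list alone), with a shift of -0.15 (adjusted p = 0.03; adjusted p = 0.43 with an estimated correlation). The fallers with the smallest p were gsh0 (-1.86 ± 0.13, adjusted p = 8.5e-05), glutathione reductase (-1.15 ± 0.16, adjusted p = 0.001), the glutathione transferase gsto1 (-1.23 ± 0.19, adjusted p = 0.0018) and gsh1 (-0.86 ± 0.14, adjusted p = 0.0021). Both gsh0 and gsh1 are subunits of the enzyme that starts glutathione synthesis. The call for this list was also lost with quantile normalization of the processed signal (adjusted p = 0.051), with the mean of all probes of a gene (0.087), and without MD Born 1 (0.11), HD Born 1 (0.053) or HD Born 2 (0.082). Its shift ran from -0.08 without HD Born 1 and -0.09 without HD Born 2 to -0.24, -0.25 and -0.29 without HD Troutlodge 1, HD Troutlodge 2 and MD Troutlodge 1.

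**Figure D2:**
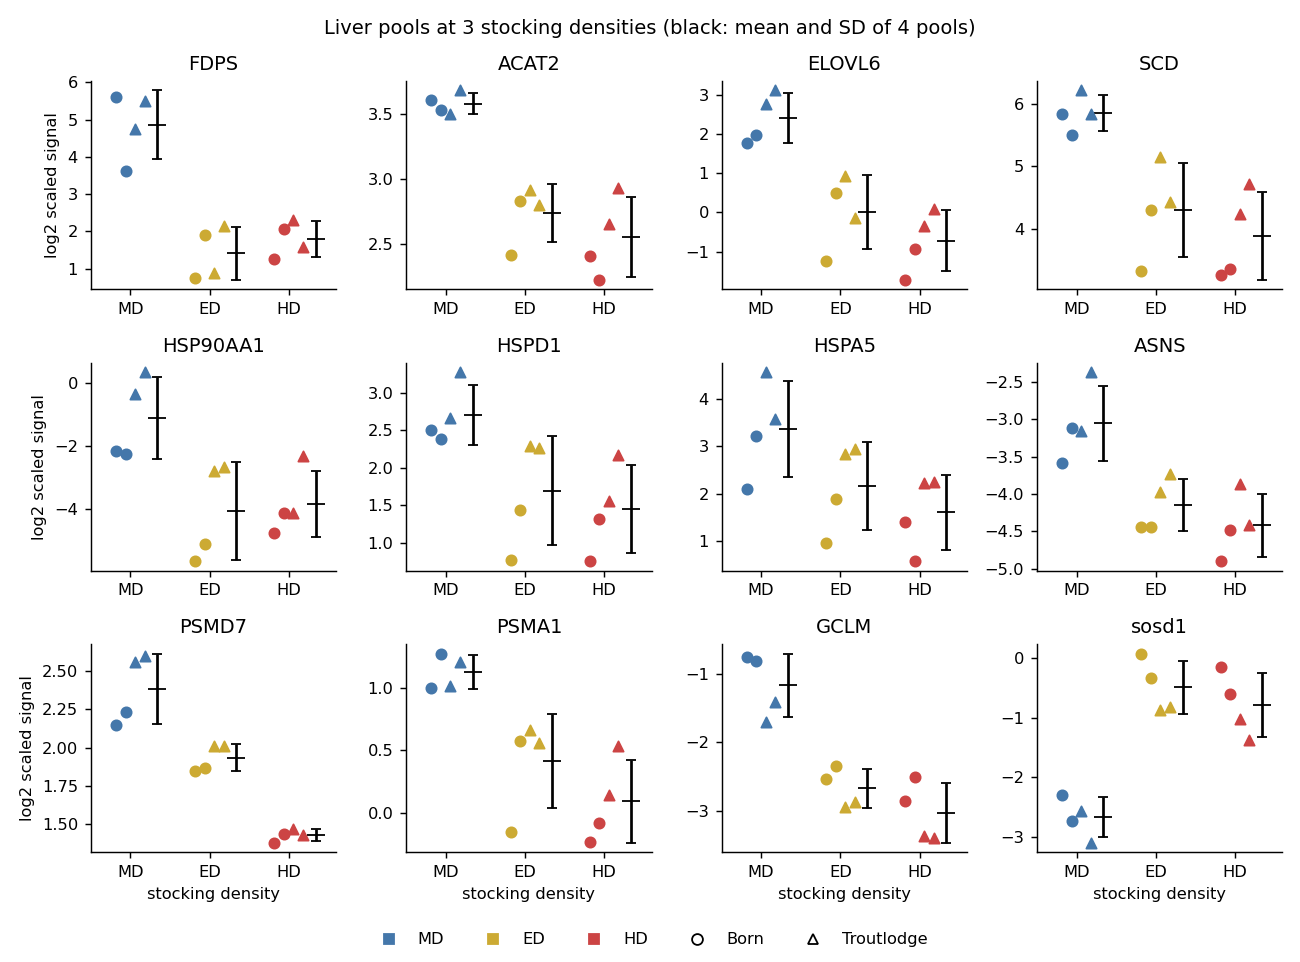
Log2 signal relative to the array's 75th percentile of 12 genes in liver at MD, ED and HD, with a point for each pool of 5 fish, shaped by strain, and the mean and SD of the 4 pools of a density. The panels use human gene names: FDPS is fpps, ACAT2 thic, HSP90AA1 hs90a, HSPD1 hsp60, HSPA5 grp78, ASNS asparagine synthetase and GCLM gsh0. The lipid synthesis, chaperone, proteasome and glutathione genes had lower means at ED and HD than at MD, and sosd1 a higher one.

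Other genes rose at high density in liver. Sclerostin domain-containing protein 1 (sosd1), a secreted inhibitor of growth factor signalling, was 3.67-fold higher (1.87 ± 0.19, adjusted p = 3e-04). Histidine decarboxylase (hdc), which makes histamine, was above background in 4 of 4 HD pools and 0 of 4 MD pools and at least 2.62-fold higher (adjusted p = 0.0021). The catalytic subunit of glucose-6-phosphatase (G6PC), the last step of glucose release by the liver, rose by 1.23 ± 0.21 (adjusted p = 0.0027), and phosphoenolpyruvate carboxykinase 1 (PCK1), which starts glucose synthesis, by 1.14 ± 0.35 (adjusted p = 0.041, above background in 3 of 4 MD pools). Perforin, a pore-forming protein of cytotoxic lymphocytes, rose by 1.02 ± 0.14 (adjusted p = 0.001), and the growth hormone receptor ghr1 by 0.72 ± 0.16 (adjusted p = 0.012).

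The remaining genes with the largest rises were polr3gl (1.56 ± 0.23, adjusted p = 0.0014, above background in 1 of 4 MD pools), fgl2 (1.51 ± 0.31, adjusted p = 0.0073, 2 of 4 MD pools) and sphm (1.57 ± 0.36, adjusted p = 0.013, 3 of 4 HD and 1 of 4 MD pools). Above background in 0 of 4 MD pools were jmy, at least 1.71-fold higher and measured in 3 HD pools (adjusted p = 0.0066), hebp1, at least 1.52-fold higher in 3 (adjusted p = 0.04), and p3ip1, at least 1.36-fold higher in 2 (adjusted p = 0.023). Angiogenin ang1 was measured in 2 of 4 HD pools and 0 of 4 MD pools (adjusted p = 0.041), with changes of 3.57 in Born and 0.35 in Troutlodge. Without 1 array the call of ang1 was lost in 9 of 12 fits (highest adjusted p = 0.14 without HD Born 1), that of hebp1 in 6 (0.11 without MD Troutlodge 2) and that of p3ip1 in 4 (0.074 without HD Born 1). Slide as a block ended the calls of ang1 (0.056) and hebp1 (0.098). A probe of muscle glycogen phosphorylase, pygma, rose by 1.68 ± 0.26 (adjusted p = 0.0018), while another probe named for the muscle form changed by 0.13 ± 0.18. Further falls were those of the mitochondrial ATPase atad3, 4.11-fold lower (adjusted p = 0.00078), and atna (-2.44 ± 0.28, adjusted p = 0.00052, above background in 3 of 4 HD pools). Also lower were the DNA replication factor psf1 (-2.32 ± 0.37, adjusted p = 0.0021, 1 of 4), the stress granule protein g3bp2 (-1.96 ± 0.41, adjusted p = 0.0082, 3 of 4) and the RNA exosome subunit exos6, at least 1.53-fold lower (adjusted p = 0.014, 0 of 4 HD and 3 of 4 MD pools). With normexp and quantile normalization the sizes were smaller for such dim genes, with -1.23 for atna, -0.81 for psf1, -0.88 for g3bp2, 0.56 for pygma, 0.33 for polr3gl and 0.36 for fgl2.

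Ribosomal protein genes were the only list called higher in HD livers, with 3 of 56 rising, 2 when adjusted over the list alone, and a shift of 0.04 (adjusted p = 0.0069; adjusted p = 0.63 with an estimated correlation). Its direction flipped to -0.02 with normexp and quantile normalization (adjusted p = 0.94) and to -0.06 with quantile normalization of the processed signal (0.99), and its call was lost with the percentile over all probes (0.13) and without MD Troutlodge 2 (0.093), where the shift was -0.01. The shift was 0.02 without HD Born 1 and 0.07 without MD Born 1 or MD Troutlodge 1. Glucose metabolism had 6 of 20 members higher and 1 lower (9 and 1 when adjusted over the list alone), and its shift of 0.15 did not pass (adjusted p = 0.27). The lower member was phosphoglycerate mutase PGAM1, a step of glycolysis (-1.10 ± 0.18, adjusted p = 0.0025), of whose other probes 1 rose. The glucocorticoid-responsive genes, 5 measured, shifted by -0.23 (adjusted p = 0.64), and 1 rose. A dim probe with the symbol fkbp5, a gene of this list, was lower in HD livers (-1.65, adjusted p = 0.0073). For the interferon and antiviral list the shift was -0.30 (adjusted p = 0.07), with 1 of 19 lower, and for the acute-phase and complement list 0.02 (adjusted p = 0.25), with 2 of 23 higher. Cell cycle genes shifted by -0.25 (adjusted p = 0.16), with 4 of 22 lower, led by the replication helicase mcm4 (-1.53 ± 0.28, adjusted p = 0.0041), and 2 higher. Markers of hepatocytes shifted by 0.09 (adjusted p = 0.096), of B cells by 0.21 (adjusted p = 0.30) and of T cells and natural killer cells by 0.24 (adjusted p = 0.27). The B cell score was 0.13 to 0.30 in HD pools and -0.25 to -0.03 in MD pools, and that of 3 thrombocyte markers, too few to test, 0.10 to 0.26 and -0.53 to 0.01. Markers of exocrine pancreas, a digestive gland next to the liver, shifted by 1.11 without passing (adjusted p = 0.061), with 1 of 6 higher and 5 of 6 when adjusted over the list alone.

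In the test over all 20718 probes, 2129 rose and 1606 fell in HD against MD, and 7174 had an unadjusted p under 0.05. The median change of all probes was 0.14, and 0.02 with either quantile setting, so list shifts are given relative to all genes. The split between rises and falls turned with the scaling, to 1502 and 1894 with normexp and quantile normalization, 1524 and 1862 with quantile normalization of the processed signal, and 1135 and 2219 with the percentile over all probes. Fitted with slide as a block, 1298 probes rose and 1348 fell, and within slide 3, the only slide with both strains at both densities, 9 rose and 21 fell. In the blocked fit the shifts of cholesterol synthesis, fatty acid synthesis, proteasome, endoplasmic reticulum stress, chaperone, antioxidant and ribosomal lists were -1.16, -1.32, -0.57, -0.92, -0.39, -0.21 and 0.05, all past the threshold. In the same order, they were -1.20, -1.03, -0.62, -0.71, -0.07, -0.42 and 0.05 within slide 1 (Born alone) and -1.19, -1.44, -0.46, -0.68, -0.60, -0.23 and 0.07 within slide 3. All these lists take members by symbol or protein name. By symbol alone 0 of 14 lists passed with camera or with an estimated correlation, 1 passed with fry, and both lipid synthesis lists had too few members to test. The count was 1809 without HD Troutlodge 1, 2101 without MD Troutlodge 2, 2257 without HD Born 1 and 2409 without HD Troutlodge 2.

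**Figure D3:**
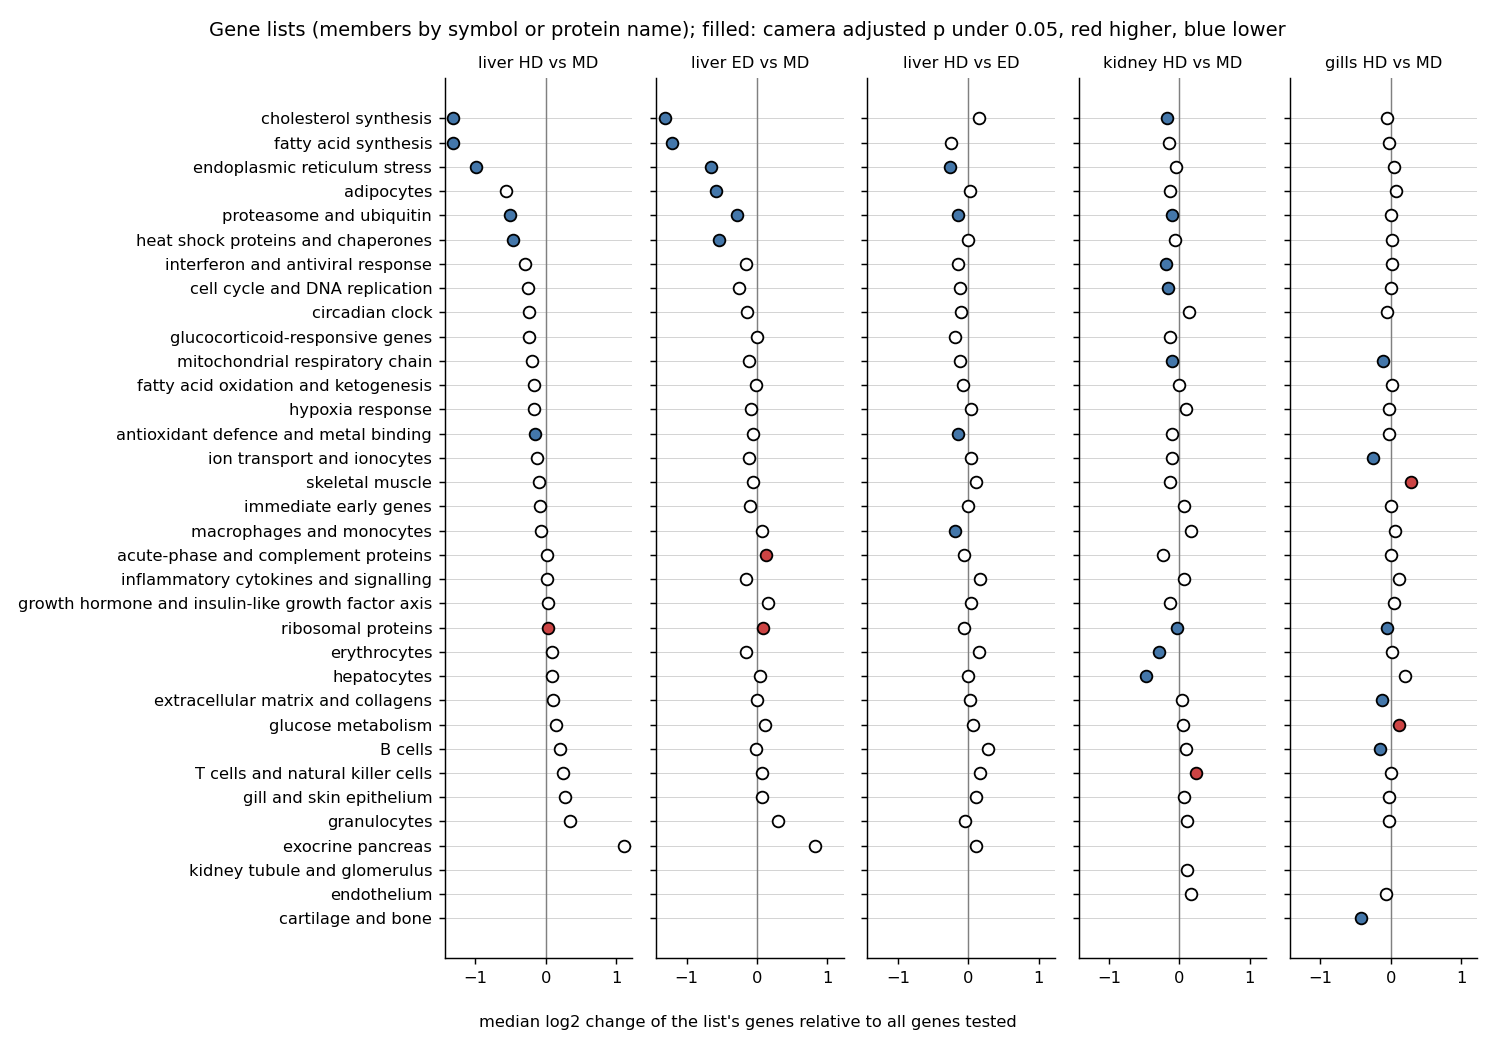
Median log2 change of each gene list relative to all genes (horizontal axis) in the density comparisons, with members found by symbol or protein name and filled points for lists past the camera threshold. Cholesterol and fatty acid synthesis lie lowest in liver, at -1.31 and -1.31 in HD and -1.31 and -1.20 in ED against MD.

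At the elevated density, liver showed much of the same falls. The gene fpps was 10.9-fold lower in ED than in MD (-3.45 ± 0.43, n = 4 pools each, adjusted p = 0.0016), erg19 7.94-fold lower (adjusted p = 0.0016) and squalene synthase (fdft), the next step towards sterols, changed by -2.38 ± 0.40 (adjusted p = 0.0047, above background in 1 of 4 ED pools). Of 12 cholesterol synthesis genes 9 fell, 0 rose and 3 did not pass, 10 falling when adjusted over the list alone, including mevalonate kinase (-1.89 ± 0.40, adjusted p = 0.015). Of 10 fatty acid synthesis genes 6 fell, 0 rose and 4 did not pass (7 when adjusted over the list alone), including ELOVL6 (-2.41 ± 0.34, adjusted p = 0.0026) and ATP-citrate synthase, which supplies acetyl-CoA for both pathways (-1.14 ± 0.19, adjusted p = 0.0043). The shifts were -1.31 for cholesterol synthesis (adjusted p = 8e-09; adjusted p = 0.12 with an estimated correlation) and -1.20 for fatty acid synthesis (adjusted p = 1.5e-08), which kept its call with an estimated correlation (adjusted p = 0.028). With normexp and quantile normalization the cholesterol shift was -0.67 and fdft stood at -0.72.

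Among chaperones, 6 of 16 fell, 0 rose and 10 did not pass (7 when adjusted over the list alone), and the list shifted by -0.54 (adjusted p = 0.00014; adjusted p = 0.27 with an estimated correlation). Here hs90a stood at -2.95 ± 0.38 (adjusted p = 0.0019, above background in 3 of 4 ED pools) and the co-chaperone STIP1 at -1.34 ± 0.22 (adjusted p = 0.0043). In endoplasmic reticulum stress 5 of 12 fell and 7 did not pass (5 fell and 1 rose when adjusted over the list alone), with the chaperone hyou1 at -1.76 ± 0.39 (adjusted p = 0.018). Their shift was -0.65 (adjusted p = 0.00092; adjusted p = 0.38 with an estimated correlation). Of 24 proteasome genes 7 fell, 0 rose and 17 did not pass (8 when adjusted over the list alone), including PSMA6 (-0.61 ± 0.12, adjusted p = 0.011). The proteasome shift was -0.29 (adjusted p = 5.3e-05; adjusted p = 0.45 with an estimated correlation). Ribosomal proteins (0.09, 3 of 56 higher, adjusted p = 4.2e-05; adjusted p = 0.57 with an estimated correlation) and the acute-phase and complement list (0.13, 1 of 23 higher, adjusted p = 0.031; adjusted p = 0.52 with an estimated correlation) shifted upward. Adipocyte markers shifted by -0.58 with 1 of 6 lower (adjusted p = 0.04; adjusted p = 0.38 with an estimated correlation). These last 3 calls were lost with both quantile settings, and the ribosomal shift was then 0.02 with normexp and -0.02 without it. The acute-phase call was also lost without MD Born 1 (0.17), MD Born 2 (0.063) or ED Born 1 (0.27). The adipocyte call was lost with the value table (0.052), the percentile over all probes (0.055) and without MD Born 1 (0.086), MD Troutlodge 2 (0.067) or ED Troutlodge 1 (0.15). With normexp and quantile normalization the endoplasmic reticulum, proteasome and adipocyte shifts were -0.26, -0.18 and -0.27. Without MD Troutlodge 1 the endoplasmic reticulum shift was -0.42 and the acute-phase shift 0.21, without MD Troutlodge 2 the ribosomal shift was 0.05 and the adipocyte shift -0.35, and without ED Born 2 the ribosomal shift was 0.14. Pancreas markers shifted by 0.83 without passing (adjusted p = 0.055).

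Besides these, sosd1 rose 4.53-fold (2.18 ± 0.19, adjusted p = 0.00063), G6PC by 1.24 ± 0.21 (adjusted p = 0.0047), and txnip, which binds thioredoxin, 2.65-fold (1.41 ± 0.26, adjusted p = 0.0071). The gene hdc was at least 2.6-fold higher (adjusted p = 0.0041, 4 of 4 ED and 0 of 4 MD pools above background), and pygma (1.55), sphm (1.48) and polr3gl (1.45) rose as well. Above background in 0 of 4 MD pools were p3ip1, at least 1.61-fold higher and measured in 3 of 4 ED pools (adjusted p = 0.022), jmy, at least 1.32-fold in 2 (0.029), and rufy2, at least 1.08-fold in 2 (0.031). The creatine-synthesis enzyme gamt rose by 1.29 ± 0.35 (adjusted p = 0.043), a call lost with slide as a block (0.069), normexp (0.052), the value table (0.052), no filter (0.084) and no trend (0.069). It was also lost without 1 array in 7 of 12 fits, with the highest adjusted p of 0.13 without MD Troutlodge 2 (1.07). Further calls lost without 1 array were those of rufy2 in 6 fits (at most 0.098, without ED Troutlodge 2), jmy in 6 (0.086, ED Troutlodge 1), sphm in 4 (0.079, ED Troutlodge 2) and p3ip1 in 4 (0.07, ED Born 1). Further falls were lipe at 8.58-fold (adjusted p = 0.0035), hsp74 (-2.77 ± 0.46, adjusted p = 0.0046, above background in 2 of 4 ED pools), atad3 (-1.94 ± 0.26, adjusted p = 0.0023) and g3bp2 (-1.92 ± 0.33, adjusted p = 0.0051). The co-chaperone fkbp5 was at least 1.72-fold lower (adjusted p = 0.0054, above background in 0 of 4 ED and 3 of 4 MD pools), and the nuclear export receptor xpo1 at least 1.02-fold lower (adjusted p = 0.027, 0 of 4 and 2 of 4), a call lost with slide as a block (0.054) and in 5 of 12 fits without 1 array (0.092 without MD Troutlodge 2). With slide as a block, jmy (0.074) and sphm (0.065) lost theirs too. With normexp and quantile normalization hs90a stood at -1.68, hsp74 at -0.93, fkbp5 at -0.34, xpo1 at -0.31 and hdc at 0.41.

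In all, 714 of 20718 probes rose and 910 fell in ED against MD, 4974 had an unadjusted p under 0.05, and the median change was 0.10. The split was 513 and 1019 with normexp and quantile normalization and 471 and 1122 with the percentile over all probes. A block for slide left 525 that rose and 764 that fell, and within slide 3 alone limma called 0. The blocked shifts of cholesterol synthesis, fatty acid synthesis, proteasome, chaperones, endoplasmic reticulum stress, ribosomal and acute-phase lists were -1.11, -1.22, -0.34, -0.59, -0.47, 0.10 and 0.16 and passed, and that of adipocytes, -0.39, did not (adjusted p = 0.15). In that order with adipocytes last, slide 1 gave -1.27, -1.19, -0.44, -0.27, -0.85, 0.19, 0.47 and -0.34, and slide 3 gave -0.79, -1.21, -0.38, -0.55, -0.54, 0.08, 0.07 and -0.45. The count was 815 without ED Troutlodge 2, 875 without MD Troutlodge 2, 934 without ED Born 1 and 1041 without MD Born 2.

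The changes at both densities overlapped. Of probes called in both comparisons 592 rose in both and 812 fell in both, and 0 went in opposite directions. Independent lists would give 73 and 71, but lists that share the MD pools are not independent. Because both comparisons share the MD pools, the correlation of their log2 changes across probes, 0.82 with a covariance of 0.206, was set beside a simulation with no effect, which gave 0.50 and 0.042. With the MD pools split between the comparisons, the correlation was 0.52 to 0.62 and the covariance 0.154 to 0.173. Across probes, which are not independent replicates, 83.2% had the same sign, against 66.8% in the simulation.

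Between high and elevated density no gene passed in liver. The symbols with the smallest p were the kinase fyn (0.71, adjusted p = 0.73) among higher values and iron-responsive element-binding protein ireb1 (-0.49, adjusted p = 0.73) and the glutathione transferases gsta3 (-0.44) and gsto1 (-0.69) among lower ones. The proteasome subunits PSMD7 (-0.50 ± 0.10) and PSMB6 (-1.08 ± 0.22) did not pass over all probes (adjusted p = 0.59 each) and did when adjusted over the list alone. With camera, 4 lists were lower in HD than in ED: proteasome (-0.15, adjusted p = 0.0019), antioxidant defence (-0.15, adjusted p = 0.014), macrophages and monocytes (-0.19, adjusted p = 0.014) and endoplasmic reticulum stress (-0.26, adjusted p = 0.026). All of them lost the call (adjusted p = 0.57 with an estimated correlation), and fry called 0 of them. With the mean of all probes of a gene, the antioxidant (adjusted p = 0.12), macrophage (0.12) and endoplasmic reticulum calls (0.33) were lost as well. Leaving out HD Born 1 (0.071) or HD Born 2 (0.063) ended the antioxidant call, and leaving out ED Troutlodge 2 (0.14) the macrophage call. The endoplasmic reticulum call ended without ED Born 2 (0.33), ED Troutlodge 1 (0.096), HD Troutlodge 1 (0.14) or HD Troutlodge 2 (0.079) and with the value table (0.054). Its shift was -0.15 without ED Born 2 and -0.13 without HD Troutlodge 1, and the macrophage shift was -0.30 without ED Troutlodge 1. By symbol alone the macrophage list, 6 members at -0.23, passed (adjusted p = 0.04; adjusted p = 0.44 with an estimated correlation). Over all probes limma called 0, with 1398 at an unadjusted p under 0.05 and a smallest adjusted p of 0.21.

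In kidney, no single gene passed between HD and MD. Transferrin (trf), a liver-made plasma protein, had the smallest p among lower genes (-2.57 ± 0.32, n = 4 pools each, adjusted p = 0.12), followed by hsp74 (-0.73 ± 0.09, adjusted p = 0.12) and s20aa (-0.87 ± 0.12, adjusted p = 0.15). Among higher genes, pygma (2.61 ± 0.40), sosd1 (1.12 ± 0.19), dab2 (0.40 ± 0.07), s28a3 (0.68 ± 0.12) and dhrs1 (0.69 ± 0.13) had adjusted p between 0.16 and 0.18. Of the planned lists by symbol, 3 of 17 passed. Hepatocyte markers, 7 members, were lower by a median of -0.55 (adjusted p = 0.012; adjusted p = 0.52 with an estimated correlation), led by apolipoprotein A-I (-2.19 ± 0.38) and serum albumin (-2.32 ± 0.54). Hypoxia genes, 6 members including the collagen hydroxylase P4HA2 (0.37 ± 0.09), were higher by 0.25 (adjusted p = 0.019; adjusted p = 0.51 with an estimated correlation). Erythrocyte markers, 6 members, were lower by -0.23 (adjusted p = 0.019; adjusted p = 0.52 with an estimated correlation). Slide as a block ended the calls of hypoxia (0.19, adjusted p = 0.16) and erythrocytes (-0.14, adjusted p = 0.23) and kept that of hepatocytes (-1.04), and fry called 0 of the 3. Within slides 2, 5 and 6 the shifts were 0.22, 0.27 and 0.07 for hypoxia, -0.10, -0.23 and 0.01 for erythrocytes, and -0.58, -0.94 and -2.26 for hepatocytes.

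With members by protein name too, 9 of 32 lists passed in kidney. Each was lost (adjusted p = 0.65 with an estimated correlation), and fry called 0 of them. Those lower were erythrocytes (-0.29, adjusted p = 0.00014), with alpha globin at -0.22 ± 0.08, proteasome (-0.11, adjusted p = 0.00014), hepatocytes (-0.47, adjusted p = 0.0016), and respiratory chain (-0.11, adjusted p = 0.002). Lower with a larger p were cell cycle (-0.16, adjusted p = 0.012), ribosomal proteins (-0.04, adjusted p = 0.017), interferon response (-0.19, adjusted p = 0.017), with the ubiquitin-like ISG15 at -0.65 ± 0.21, and cholesterol synthesis (-0.18, adjusted p = 0.036), with hmdh at -0.34 ± 0.06. Markers of T cells and natural killer cells were higher (0.23, adjusted p = 0.002), with the co-receptor CD8A at 0.70 ± 0.20. None of the members named here passed over all probes. The hypoxia shift was 0.09 and no longer passed with these members (adjusted p = 0.21).

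Of 25547 kidney probes, limma called 0 between HD and MD, 3534 had an unadjusted p under 0.05, and the median change was -0.03. When slide was a block, cell cycle (-0.04, adjusted p = 0.39), ribosomal (-0.02, adjusted p = 0.29) and respiratory chain lists (-0.07, adjusted p = 0.055) lost the call, while erythrocytes (-0.13), proteasome (-0.08), hepatocytes (-0.72), T cells (0.14), interferon (-0.15) and cholesterol synthesis (-0.17) kept it. Within slides 2, 5 and 6 the shifts were -0.15, -0.21 and 0.01 for erythrocytes, -0.21, -0.07 and 0.02 for proteasome, -0.21, -0.72 and -1.39 for hepatocytes, and 0.32, 0.11 and 0.08 for T cells. Leaving out MD Troutlodge 2 ended the calls of cell cycle (adjusted p = 0.11), interferon (0.24), ribosomal (0.15) and cholesterol lists (0.11), and leaving out MD Born 2 those of cell cycle (0.21), respiratory chain (0.065), ribosomal (0.065) and cholesterol lists (0.066). Without HD Born 2, the cell cycle (0.086), interferon (0.057) and ribosomal calls (0.23) ended. The same happened without HD Troutlodge 2 to the interferon (0.10), ribosomal (0.058) and cholesterol calls (0.06), and without MD Born 1 to the ribosomal call (0.24). The cholesterol call also ended without MD Troutlodge 1 (0.09) or HD Troutlodge 1 (0.10), with the mean of all probes (0.097) and with the percentile over all probes (0.058). The ribosomal call was lost with that percentile (0.11) and with normexp and quantile normalization (0.94). The proteasome shift ran from -0.06 without HD Born 1 to -0.17 without HD Troutlodge 1 and -0.18 without MD Troutlodge 1, and the respiratory chain shift was -0.05 without MD Born 2 or HD Born 1. Without MD Born 2 the erythrocyte shift was -0.19 and the cell cycle shift -0.08, and the interferon shift was -0.06 without MD Troutlodge 2 and -0.09 without HD Born 2. The ribosomal shift was -0.02 without MD Born 1 or HD Born 2 and -0.09 without MD Troutlodge 1 or HD Troutlodge 1. The hepatocyte shift was -0.30 without HD Troutlodge 1 and -0.28 without MD Troutlodge 1, the pool with the highest hepatocyte score (adjusted p = 0.027).

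**Figure D4:**
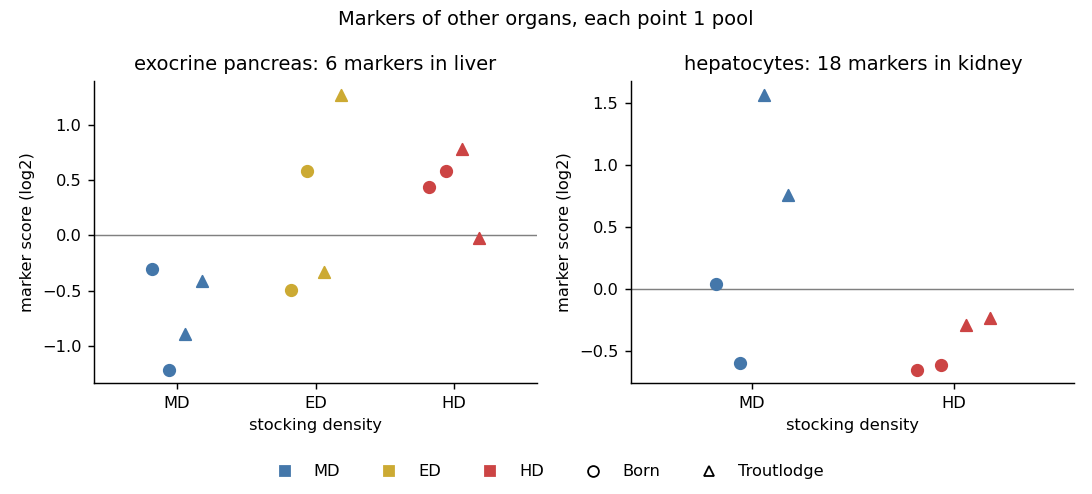
Score of 6 exocrine pancreas markers in liver and of 18 hepatocyte markers in kidney (vertical axis, log2), with a point for each pool of 5 fish, coloured by density and shaped by strain. The hepatocyte score was 1.57 and 0.76 in the Troutlodge MD kidney pools and 0.04 and -0.60 in the Born MD pools, against -0.65 to -0.23 in the HD pools.

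In gills, no gene with a name passed between HD and MD. FXYD11 (fxyd11b), a small membrane protein of gill ionocytes, stood at -0.45 ± 0.07 in HD against MD (n = 4 pools each, adjusted p = 0.22), the chloride channel CFTR at -1.02 ± 0.23 (adjusted p = 0.51) and the anion exchanger SLC4A1 at -0.45 ± 0.12 (adjusted p = 0.55). None of them passed over all probes, and 4 of 16 ion transport genes were lower when adjusted over the list alone. The ion transport list shifted by -0.25 (adjusted p = 0.00011, and 0.29 with an estimated correlation), and fry gave an adjusted p of 0.034. With normexp and quantile normalization the shift was -0.13. Skeletal muscle genes were higher by 0.29 (15 members, 2 of them when adjusted over the list alone, adjusted p = 1.4e-05; adjusted p = 0.31 with an estimated correlation), with desmin, a muscle filament protein, at 0.55 ± 0.14 (adjusted p = 0.55) and pygma at 2.50 ± 0.40 (adjusted p = 0.22). That pygma probe was higher alike in liver, kidney and gills of both strains, which a sequence difference under the probe could also give.

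Further gill lists by symbol or protein name were lower for respiratory chain (-0.11, 19 members, adjusted p = 1.4e-05), B cells (-0.15, 7 members with IGHM at -0.60 ± 0.17, adjusted p = 0.0004) and ribosomal proteins (-0.05, adjusted p = 0.0063). With an estimated correlation their adjusted p was 0.29, 0.29 and 0.93. Also lower were extracellular matrix (-0.13, adjusted p = 0.027) and cartilage and bone (-0.43, with the collagen COL10A1 at -0.63 ± 0.09, adjusted p = 0.041). Their adjusted p with an estimated correlation was 0.29 and 0.30. Glucose metabolism was higher by 0.11 (adjusted p = 0.016; adjusted p = 0.31 with an estimated correlation), with fructose-bisphosphatase FBP1 at 0.55 ± 0.10. By symbol alone 0 of 17 lists passed. Of the 8 lists, fry called ion transport, respiratory chain, extracellular matrix and cartilage, and not muscle (adjusted p = 0.25), B cells (0.075), glucose metabolism (0.14) or ribosomal proteins (0.79). Other genes with the smallest p were csrp3 (1.19 ± 0.17, adjusted p = 0.20), aldoa, uevld and tpd53 among higher values, and igfbprp1, serph, glna and aakg1 among lower ones.

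The test over 25357 gill probes called 2, both higher and both without a gene name: A_05_P327892 (1.04 ± 0.10) and A_05_P396277 (0.94 ± 0.09), each with an adjusted p of 0.049 and each named because the count was so small. A further 1727 had an unadjusted p under 0.05, and the median change was -0.01. In the fit with slide as a block, and within slides 4 and 5, limma called 0. The ion transport shift was -0.25 with that block and -0.26 and -0.20 within slides 4 and 5, and the muscle shift 0.29, 0.28 and 0.32. The block ended the calls of extracellular matrix (adjusted p = 0.050) and cartilage (adjusted p = 0.14). Both also lost it with normexp and quantile normalization (0.057 each) and without MD Born 2 (0.072 and 0.07), MD Troutlodge 1 (0.062 and 0.083) or HD Troutlodge 1 (0.067 and 0.12). The matrix call was lost without HD Born 2 (0.059), and the cartilage call without MD Troutlodge 2 (0.099) or HD Troutlodge 2 (0.077). Glucose metabolism lost it with the mean of all probes (0.12) and without MD Born 2 (0.072) or HD Born 1 (0.11). The ribosomal shift was 0.00 with either quantile setting, and its call was lost without MD Born 2 (0.07), MD Troutlodge 2 (0.32) or HD Born 2 (0.36). It was -0.08 without MD Troutlodge 1 and -0.02 without HD Born 2, where the cartilage shift was -0.27.

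More genes were called between densities in liver than in kidney or gills, and the difference between tissues was tested directly. For fpps the change was -3.07 in liver, -0.04 ± 0.11 in kidney and -0.03 ± 0.12 in gills, and it differed between liver and kidney (adjusted p = 0.00053) and between liver and gills (adjusted p = 0.00019). The change of hs90a also differed from that in kidney (-0.55 ± 0.13, adjusted p = 0.0038) and gills (-0.06 ± 0.18, adjusted p = 0.00032). For sosd1, the rise in liver differed from the -0.37 ± 0.11 of gills (adjusted p = 1.2e-05) and did not pass against kidney (adjusted p = 0.067). No difference was called for pygma (adjusted p = 0.29 against kidney and 0.33 against gills).

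In the joint fit, chosen after the results by tissue were seen, the HD against MD change differed between liver and kidney for 2075 of 19675 probes and between liver and gills for 2908 of 19223. Of 3581 probes called in liver and tested in both, 1693 differed from kidney, and of 3535, 2374 differed from gills. Picking probes by their liver call raises these shares. A joint fit also raised the count within liver, to 6486. Across probes, the liver changes correlated with those of kidney at r = 0.21 (rho 0.20) and with those of gills at r = 0.06 (rho -0.01), and kidney and gills correlated at r = 0.32 (rho 0.28).

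Within each strain, the liver falls of lipid synthesis were present in both. Troutlodge HD livers had fpps at -3.43 in the largest falls, by another probe than the -3.18 of the probe used elsewhere here, followed by hs90a (-3.22), hsp74, lipe and erg19 (-2.83). Born HD livers had fpps (-2.96, adjusted p = 0.032), erg19 (-2.92, adjusted p = 0.023), psf1, at least 4.49-fold lower, the mitochondrial carboxykinase pck2 (-2.48) and atna (-2.35). Rises in Troutlodge were led by ethanolamine kinase eki1, 12.8-fold higher (3.68 ± 0.38, adjusted p = 0.00066), followed by nrn1, at least 1.86-fold higher (adjusted p = 0.038), s2540 (2.57), jmy, at least 1.51-fold higher (adjusted p = 0.0072), and cdk6 (2.22). The same eki1 probe was also higher at HD in Troutlodge kidney (3.28, adjusted p = 0.068), while another eki1 probe stood at -0.09 in Troutlodge liver, so a sequence difference under the probe is possible. Those in Born were led by ang1, at least 2.74-fold higher (adjusted p = 0.015), and angl4, an inhibitor of lipoprotein lipase (2.51, adjusted p = 0.0082), followed by mmp13, at least 1.51-fold higher (adjusted p = 0.048), sosd1 (2.13) and ifm5 (2.07). Over all probes 3084 rose and 1634 fell in Troutlodge, and 392 rose and 525 fell in Born, 2 pools against 2 each. The split was 1892 and 2063 in Troutlodge with normexp and quantile normalization, 2090 and 1921 with quantile normalization of the processed signal and 1782 and 2492 with the percentile over all probes, which gave 319 and 719 in Born. A block for slide left 3355 probes in Troutlodge and 1169 in Born. The Born count of 917 was 66 without HD Born 1, 136 without MD Born 2, 179 without HD Born 2 and 222 without MD Born 1. The Troutlodge count of 4718 was 1739 without MD Troutlodge 2, 2077 without HD Troutlodge 1 and 2138 without HD Troutlodge 2. The cholesterol and fatty acid synthesis lists shifted by -0.94 and -1.03 in Born (adjusted p = 3.9e-05 and 9.4e-06; adjusted p = 0.42 and 0.22 with an estimated correlation). Those of Troutlodge shifted by -1.37 and -1.0 (adjusted p = 0.00014 and 9.1e-05; adjusted p = 0.61 and 0.60 with an estimated correlation). The blocked shifts were -0.94 and -1.03 in Born and -1.06 and -1.33 in Troutlodge.

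The difference between the strains in their density effect was not called for any gene in liver, kidney or gills, where limma called 0 of 20718, 25547 and 25357 probes. At an unadjusted p under 0.05 the counts were 4004, 2128 and 2277. The liver count depended on the setting, with 64 for normexp and quantile normalization, 117 for probes above background on every array, 1951 for a joint fit over tissues and 139 without ED Born 1. The joint fit gave 39 in kidney and 10 in gills, and leaving out 1 array gave up to 6 in kidney (MD Born 2) and 113 in gills (HD Born 1). Nearest to the threshold in liver were eki1 (3.77 ± 0.54, adjusted p = 0.055) and glyg (1.53, adjusted p = 0.055), and arl8b (-1.85, adjusted p = 0.058) in the other direction. In kidney, 20 probes rose and 7 fell in Born, among them ehd3, at least 4.44-fold higher (adjusted p = 0.034), cnt1a (1.27, adjusted p = 0.021), dhrs1 (0.99, adjusted p = 0.034) and a proteasome alpha 7 subunit (-1.58 ± 0.11, adjusted p = 0.013). In Troutlodge kidney limma called 0, with 2032 at an unadjusted p under 0.05. A block for slide left 0 in Born too, and without 1 array Born kidney ran from 4 (HD Born 1) to 80 (MD Born 2) and Troutlodge kidney up to 37 (MD Troutlodge 2). In gills, 8 rose and 3 fell in Born, including the immunoglobulin lambda constant region, at least 4.40-fold lower (adjusted p = 0.048), and limma called 0 in Troutlodge, with 1245 at an unadjusted p under 0.05. The blocked count for Born gills was 7, and without 1 array it ran from 0 (HD Troutlodge 1) to 151 (HD Born 1).

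Across all probes the HD against MD changes of Born and Troutlodge, which share no array, correlated at r = 0.36 (rho 0.34) in liver, 0.13 (rho 0.18) in kidney and -0.03 (rho -0.03) in gills. Of 18 ways to regroup the pools within strains, the real grouping gave the highest value in liver, where the next was 0.19, and in kidney, where the next was 0.10. In gills, 12 of 18 gave a value as high.

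Large differences separated the strains themselves. In liver, vitellogenin (vtg), the yolk protein that oestrogen induces in females, was higher in Troutlodge, the all-female strain (3.41 ± 0.66, adjusted p = 0.0036), as was pck2 (3.14 ± 0.30, adjusted p = 3.3e-05), and the acute-phase protein saa5 was lower (-2.78 ± 0.25, adjusted p = 2.4e-05). The other liver genes at the extremes were ari2, nop14 and g12, higher by 2.70 to 3.56, and tktl2, dcc1, stom and pax7, lower in Troutlodge. In kidney, api5, an inhibitor of apoptosis, was at least 6.73-fold higher in Troutlodge (adjusted p = 8.6e-06), apolipoprotein B (apob) higher by 4.16 (adjusted p = 0.0015, above background in 1 of 4 Born pools) and fxyd11b lower (-5.03 ± 0.62, adjusted p = 0.0015, above background in 1 of 4 Troutlodge pools). Carried-over liver is not excluded for apob, since serum albumin was highest in the Troutlodge MD kidney pools. Gills showed api5 at least 10.2-fold higher (adjusted p = 0.00021) and bca3 and kat3 at least 3.39-fold and 3.07-fold lower, and both genes were also among the largest falls in kidney.

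Between strains, 2107 of 20718 liver probes were higher in Troutlodge and 2603 lower, 1934 and 1814 of 25547 in kidney, and 1641 and 1643 of 25357 in gills. Fitted with slide as a block, 3487 passed in liver and 3380 in gills, but 90 higher and 34 lower in kidney, where slides 2 and 5 held a single strain each. Strain here stands for strain, run, age and sex together.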

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

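In this part, the test of a lower share of hepatocytes, the joint fit over tissues and the use of protein names in gene lists were chosen after the results had been seen, and the other tests were written before.

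Over 16 measures, 4 groups of 4 arrays (a tissue at a density) held an array far from the other 3. Chance does so in about 1 in 20 groups, or 5.3 of those tested. The liver pool MD Troutlodge 2 had 40.6% of probes above background against 38.3% to 38.6% in the other MD liver pools. The kidney pool MD Troutlodge 1 had 60.9% against 49.3% to 50%. In the liver pool HD Born 1 the 75th percentile of signal was 458 against 496 to 503. The score of kidney tubule and glomerulus markers was -0.28 in the kidney pool HD Born 1 against 0.13 to 0.18.

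In the joint fit the effect of high density differed between liver and kidney for 2075 probes, 1076 higher and 999 lower in liver. It differed between liver and gills for 2908. A joint fit also raised the liver count from 3735 to 6486. Of 92 named genes picked by their call in liver, 54 of 89 tested differed from kidney and 65 of 87 from gills.

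Other splits of the same arrays into groups of the same sizes were fitted to ask whether chance can be excluded for a count. For liver, HD against MD, the real split gave 3735 probes and the highest other split 0, so 1 of 35 splits gave as many. For ED against MD the real split gave 1624 and the highest other 1, again 1 of 35. The real split is always counted, so 1 of 35 is the lowest share possible, and chance is not excluded for either. The other splits mix the densities, which adds any density effect to their spread and lowers their counts. For liver, HD against ED, 35 of 35 gave as many as the real 0, and the highest other, 490, was the split by strain. For kidney it was 34 of 34 with the real 0, the highest other giving 2. A count of 0 is met by any split, so neither says anything on chance. For gills, 2 of 34 gave as many as the real 2, so chance cannot be excluded. The other was the split by slide, and so by pool number, with 238, which points to a structure of the samples by slide, and with slide as a block 0 passed. The strain comparison stood highest in liver (4710, 1 of 100 drawn splits, highest other 2569), kidney (3748, 1 of 34, highest other 1) and gills (3284, 1 of 34, highest other 154). These too are the lowest shares possible, so chance is not excluded there either.

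The joint fall of lipid synthesis, chaperone, endoplasmic reticulum and proteasome genes in crowded livers was weighed against 3 technical sources. A slide effect as the whole source is argued against by 2646 probes passing with slide as a block, 70.8% of the count, and by 5 of 5 lists keeping their call there. Array scaling is argued against by the quantile settings. All 20 list tests over 4 scalings kept direction and call (largest adjusted p of the 5 lists 0.0034). Shifts shrank to -0.64 for cholesterol synthesis and -0.53 for endoplasmic reticulum stress. The percentile over all probes adds a constant per array, so it is no test. A lower hepatocyte share, as from more blood cells (B cells 0.21), is argued against as the source. Hepatocyte markers did not fall with the lists (0.09 relative to all genes), but a moderate loss, lowering all genes too, is not excluded. A response of the liver to density is a hypothesis that these values leave open. They also leave open a tank difference, since tank and density go together, and fewer fat cells (markers at -0.56, adjusted p = 0.075). The lists' calls rest on a preset correlation between genes, and with an estimated one the adjusted p in HD against MD was 0.06 to 0.32.

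Transcripts of neighbouring organs varied between pools. In liver, trypsin I (1.52 ± 0.52), elastase-1 (1.40 ± 0.50), chymotrypsin B (1.12 ± 0.42) and 3 further pancreas markers moved together between pools of the same group, with a median pairwise correlation of 0.64 (random probe sets of like signal had a median of -0.01 and a highest value of 0.55 in 1000), so pancreatic tissue carried along in some pools may contribute. A rise with density is not excluded: every ED and HD pool lay above every MD pool in 1 of 2 strains, which leaves both explanations open. In kidney, the hepatocyte score of the 18 markers was highest in the Troutlodge MD pools (1.57 and 0.76). Of 567 probes far brighter in liver, 36.0% were highest in MD Troutlodge 1 against 21.7% of kidney probes of like signal, 14.4 percentage points more, which is too little to tell carried-over liver from a general difference of that pool.

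Single probes differed by at least 1 on the log2 scale, the same way in all 3 tissues and without a test of each, 59 of 18960 between HD and MD in Born (0.1 expected from the shares per tissue) and 15 in Troutlodge (0 expected). Examples chosen after their values were seen were tlk2 (-2.42, -2.81 and -3.12 in Born liver, kidney and gills, and 1.01, 1.97 and 1.67 in Troutlodge) and pygma (1.85, 3.44 and 2.68 in Born). For 17 such genes with several probes, the other probes followed by a median ratio of 0.05 (95% interval from 0 to 0.10), against 0.52 for liver HD against MD, so sequence differences under single probes between the fish pooled at each density are a candidate explanation. Between strains the ratio was 0.22 in kidney and 0.17 in gills, where the same explanation would hold for many probes, and 0.29 in liver, which does not decide. Probes were matched by name and may belong to paralogs, and differences in true expression remain open for each gene.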

How the results depend on the processing

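In this part, the percentile over all probes, gene list members by protein name and the fits without arrays rich in hepatocyte or pancreas transcripts were chosen after the results were seen, and the other alternatives were planned. Over 11 to 13 alternatives per density comparison, the liver counts of HD and ED against MD stayed within 1.5 times under all but the following, and the cause was not tested unless given. With no filter on dim probes, which adds probes, counts were 2227 for liver HD against MD, 969 for ED against MD, 462 and 17 for Born liver and kidney, 35 for Born gills and 2379 for strain in kidney. With all 28 arrays in a joint fit, which shares the spread over tissues, they were 6486, 3818 and 17 for liver HD against MD, ED against MD and HD against ED, 17 for kidney and 3068, 86 and 48 for Born liver, kidney and gills. That fit gave 94 and 2 for Troutlodge kidney and gills, 1951, 39 and 10 for the difference between strains in liver, kidney and gills, and 2156 for strain in gills. Within slide 3, with fewer arrays, liver gave 30 and 0. The value table and group means gave 1 each for liver HD against ED. The 2 gill calls became 0 under both normexp and quantile settings, the value table, slide as a block, the replicate block, group means, no trend and within slides 4 and 5. Normexp with quantile normalization gave 93 for Born kidney and 64 for the liver difference between strains, quantile normalization alone 97 and 1 and the value table a count of 2 for the latter, and the strictest filter 68, 6 and 117 for Born kidney, Born gills and that difference. Slide as a block gave 0 for Born kidney, 7 for Born gills and 124 for strain in kidney, and the percentile over all probes 2 for Troutlodge kidney.

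The replicate block gave 3720 and 1646 for liver HD and ED against MD, 0 for gills, 7 for Born gills, 2 for Troutlodge kidney and 1 for the kidney difference between strains, and changed no other count by over 1.5 times. Same-numbered pools shared a slide in gills (4 or 5), where the replicate block is the slide block, and for replicate 2 in liver (3), with correlations of deviations from -0.13 to 0.20 in liver, -0.03 to 0.14 in kidney and 0.08 to 0.25 in gills. The number of gene lists passing by symbol was 1 with fry in liver HD against MD and ED against MD, where it was 0. It was 0 with an estimated correlation, fry, the mean of all probes or normexp for HD against ED (1), and 0 with an estimated correlation or fry and 1 with slide as a block for kidney (3). With protein names it was 7, 8, 4, 9 and 8 for liver HD against MD, ED against MD, HD against ED, kidney and gills. The correlation between strains was 0.45 with normexp, 0.21 with no filter and 0.28 with either replicate number alone in liver (0.36), 0.19 with normexp and 0.09 with replicate 1 in kidney (0.13), and 0.05 with replicate 1 in gills (-0.03).

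Leaving out each array in turn, with a lone pool assumed to vary like the others, counts ran from 1809 to 4657 (liver HD against MD), 815 to 1853 (ED against MD), 0 to 0 (HD against ED), 0 to 1 (kidney) and 0 to 1 (gills). Within Born they ran from 66 to 1058, 4 to 80 and 0 to 151 in liver, kidney and gills, within Troutlodge from 1739 to 4732, 0 to 37 and 0 to 3, for the difference between strains from 0 to 139, 0 to 6 and 0 to 113. For strain they ran from 3717 to 4464, 2225 to 2977 and 2019 to 2463. Lists by symbol ran from 0 to 0, 0 to 0, 0 to 2, 1 to 5 and 0 to 2 for liver HD against MD, ED against MD, HD against ED, kidney and gills, and the correlation between strains from 0.27 to 0.38, 0.07 to 0.16 and -0.09 to 0.04. For the 20 named genes of each liver comparison with MD, 188 and 186 settings kept the call and 17 and 22 lost it, most of them in genes near background such as hebp1, ang1 and p3ip1, and 5 in gamt, which lay above it in all ED and MD pools. No named gene reversed. Signal over background limits what can be seen: 38.3% to 60.9% of probes lay above it.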

Other observations

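Gene groups were called between the strains in each tissue, with members found by symbol or protein name, a choice made after results had been seen, and the tissues were not tested against each other here. In gills, 14 of 22 interferon and antiviral genes were lower in Troutlodge, 0 were higher and 8 did not pass (15 lower when adjusted over the list alone). Among them were the ubiquitin-like ISG15 (-2.43 ± 0.14, adjusted p = 4.38e-05), the antiviral GTPase mx1 (-1.79 ± 0.14, adjusted p = 0.000213) and Gig2 (-1.92 ± 0.20, adjusted p = 0.000923). That list shifted by -0.48 (adjusted p = 7e-10; adjusted p = 0.052 with an estimated correlation), with -0.48 with slide as a block and -0.50 and -0.48 within slides 4 and 5. Extracellular matrix genes were higher, 6 of 12 (7 when adjusted over the list alone), including fibronectin finc (0.86 ± 0.10, adjusted p = 0.00154) and the protease mmp2 (0.54 ± 0.07, adjusted p = 0.00176), with a shift of 0.45 (adjusted p = 0.00038; adjusted p = 0.10 with an estimated correlation), the same with the block, and 0.49 and 0.44 within those slides. The heme synthesis enzyme ALAS2 of red cells was higher as well (1.23 ± 0.20, adjusted p = 0.00603), in an erythrocyte list that shifted by 0.33 (adjusted p = 0.031; adjusted p = 0.56 with an estimated correlation), 0.33 with the block and 0.19 and 0.40 within slides. Cartilage and bone genes shifted by 0.62 (adjusted p = 0.044; adjusted p = 0.34 with an estimated correlation), a call lost with the block (adjusted p = 0.084), without MD Born 1 (0.052) and without MD Troutlodge 2 (0.056). The erythrocyte call was lost without HD Born 2 (adjusted p = 0.05), and the interferon and matrix lists kept theirs under each scaling and without any 1 array.

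In liver, chaperones were higher in Troutlodge than in Born, 8 of 16 against 1 lower (11 and 1 when adjusted over the list alone), led by hs90b (1.43 ± 0.18, adjusted p = 0.000209) and hs90a (2.02 ± 0.31, adjusted p = 0.000923). So were 8 of 12 endoplasmic reticulum stress genes, also 8 when adjusted over the list alone, led by dnjc3 (1.67 ± 0.26, adjusted p = 0.00108) and grp78 (1.37 ± 0.24, adjusted p = 0.00183). The shifts were 0.50 and 0.74 (adjusted p = 0.0012 and 0.00024, and 0.51 for both with an estimated correlation). Ribosomal proteins were lower, 36 of 56 against 1 higher (42 and 1 when adjusted over the list alone), with rpl38 at -0.55 ± 0.09 (adjusted p = 0.000971) and a shift of -0.24 (adjusted p = 1.7e-08; adjusted p = 0.71 with an estimated correlation). With slide as a block the 3 shifts were 0.50, 0.68 and -0.23, and within slides 1 and 3 they were 0.55 and 0.45, 0.92 and 0.57, and -0.24 and -0.24. In kidney, 7 of 12 endoplasmic reticulum stress genes were higher in Troutlodge (0.44, adjusted p = 0.0046; adjusted p = 0.63 with an estimated correlation; 0.28 with the block and 0.21 within slide 6) and 4 of 10 fatty acid synthesis genes (0.51, adjusted p = 0.027; adjusted p = 0.63 with an estimated correlation; 0.59 and 0.55). Called higher as well were chaperones (0.28, adjusted p = 0.027), proteasome (0.17, 0.0046), glucose metabolism (0.29, 0.049) and cell cycle (0.20, 0.027). With an estimated correlation the adjusted p of these lists was 0.73, 0.63, 0.63 and 0.73. All of these lost the call with slide as a block (0.11, 0.02, 0.24 and -0.14; adjusted p = 0.35, 0.35, 0.33 and 0.35), where cell cycle flipped. Ribosomal proteins were lower (-0.07, adjusted p = 0.037; adjusted p = 0.73 with an estimated correlation; -0.13 with the block) and flipped to 0.02 with normexp and quantile normalization (adjusted p = 0.90). Because the strains were run in separate experiments, these differences belong to strain, run, age and sex together.

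In Troutlodge kidney, 19 acute-phase and complement genes, most of them made by the liver, lay lower in HD than in MD by a median of -1.27 (adjusted p = 4.8e-08; adjusted p = 0.55 with an estimated correlation), together with 18 hepatocyte markers, 2 of them on another list and 14 above background on all 8 kidney arrays (-0.88, adjusted p = 3.4e-09; adjusted p = 0.55 with an estimated correlation). Of these genes 0 passed over all probes, and 9 and 11 were lower when adjusted over the list alone. Within slides 5 and 6 the shifts were -0.49 and -1.65 for the first list and -0.72 and -1.39 for the second, and slide as a block left them at -1.27 and -0.88. Slide 6 held MD Troutlodge 1, the pool with 60.9% of probes above background and the highest hepatocyte score, and without it the shifts were -0.88 and -0.78. Without MD Troutlodge 2 they were -1.90 and -1.40, and without HD Troutlodge 1 -0.80 and -0.96. Carried-over liver tissue is not excluded. Both differed from Born by the test of the difference (adjusted p = 2.2e-06 and 3e-05; adjusted p = 0.43 and 0.51 with an estimated correlation). No difference between strains in their density effect was called for any of 31 lists in liver.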
